A study of Mus musculus with 42 samples.

How the data were processed

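The series holds 42 bulk RNA libraries of mouse stem cell lines, made with a Smart-Seq protocol per the labels' protocols. The labels put 27 unsorted libraries into 9 groups of 3, 14 libraries into populations sorted on Cdx2-GFP, and 1 library into an unsorted C3.1 sample that stood in no comparison. The 3 libraries of an unsorted group are technical replicates by the series' design text, so every p-value measures only the spread between such libraries and not the spread between cultures. Each sorted population had 1 library.

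The deposited files hold read counts per gene symbol, 1 library per file, as whole numbers that were not normalized. Per the submitters' processing notes the tools were Trim Galore 0.5.0, Bowtie2 2.3.4.1, featureCounts of Subread 1.6.2 and DESeq2 1.18.1, and the builds named were GRCm38 (mm10) and GRCh38 (hg38), with no role given to the human build. The annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The files list 24421 gene symbols, of which 23204 were found in a RefSeq table for GRCm38, the build of the coordinates printed. Total counts per library ran from 2213748 to 3641422 (median 2907130.5), and each library had counts for 13657 to 14555 genes. At these totals a group of 3 libraries with 0 counts of a gene leaves a floor of 3 counts over the group. A fold against such a group is given as a lower bound against that floor, and a fold against a group with 1 to 3 counts as a ratio with its 95% exact interval. Bounds and intervals cover counting error only.

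All 27 pairs of technical replicates were compared by a chi-square statistic over genes with at least 20 counts. The mean per gene lay between 1.52 and 14.31, above sampling noise in every pair, so no libraries were merged. The widest pairs involved F4-GFP_iCDX2 pTX replicate 2. Correlations of log2 CPM within pairs ran from 0.9665 to 0.9876.

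Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The 27 unsorted libraries entered 1 fit with a term per group, and 11768 genes passed the filter. Differences between cell lines in the effect of a medium were interaction contrasts of that fit. The 14 sorted libraries entered a fit of their own with the parent label (the label without its last letter) as a block of 7 pairs, over 10223 genes. The 8 libraries with labels of 3 letters entered an additive model of the 3 letters, over 9246 genes. Replicate numbers of the unsorted libraries only name them, so no pairing was made among them.

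A set of 23 gene lists, covering trophoblast states, other cell types, signalling targets, metabolism, stress and imprinting, was fixed before the data were examined. The list of mitochondrially encoded genes had 0 of its 9 members in the files and was not tested, which left 22 lists. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Over all comparisons and lists 124 tests passed at the preset correlation and 53 with an estimated one. The count of called members is also given adjusted over the list alone.

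Genes were named by a rule fixed before the data were examined. It takes the 6 largest and 6 smallest log2 fold changes (3 and 3 for pTX-long against pTX, for the 2 lines in TX, for line differences and for letter positions) among genes called with an absolute log2 fold change of at least 1, at least 10 CPM in the higher group and no overlap between the libraries of both groups. For the sort the last condition was the same sign in at least 6 of 7 pairs, and line differences and letter positions had no such condition. The rule leaves out predicted genes and pseudogenes. It adds up to 4 called members of each list, those with the largest absolute change, and in every comparison Cdx2, Eomes, Elf5, Esrrb, Sox2, Gata3, Tfap2c, Krt8, Ascl2, Hand1 and Pou5f1. List members may be left out of the text where their list is given as a count. Pou5f1 did not pass the filter on low counts in any fit, and Cdx2 did not pass it in the fits of the sorted libraries.

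Reads shared with a near-identical gene cannot be placed with certainty. The share of 50-base transcript subsequences found in another gene was computed for named genes except Lincenc1, Cyr61, Rn45s and Malat1. A gene at 20% or more is called uncertain.

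The tests were checked on simulated counts in which 200 genes were changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 49.3%, 65.7% and 84.8% were called for C3.1 pTX against TX, with 4 of 137 calls false. For the line difference in the pTX effect the shares were 13.4%, 44.8% and 78.8% (6 of 97 false). For the sort (10223 genes) they were 76.1%, 94% and 100% (12 of 192 false). For the first letter (9246 genes) they were 67.2%, 92.5% and 100% (13 of 186 false). The rates may not hold with F4-GFP_iCDX2 pTX, whose libraries were spread widely.

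Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, no filter on low counts, a fit of only the groups compared, leaving out each library or pair, other blocks and subsets of the sorted libraries, other list tests, and a minimum of 10 CPM for the agreement between lines. Leaving out each library for the letter positions and for the agreement between lines in both media was added after seeing the data, as was every alternative for the called members of gene lists and the list test with each library or pair left out.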

Results

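Read counts per gene were measured in 42 bulk RNA libraries of mouse stem cells. C3.1 and F4-GFP_iCDX2 (F4 below) are cell lines grown in TX, a defined medium for trophoblast stem cells, which renew the trophectoderm lineage that forms the placenta. G4 is a mouse embryonic stem (ES) cell line kept in 2iLIF, which holds cells in naive pluripotency. Both trophoblast lines were also grown in media labelled pTX and pTX-long, whose compositions are not given in the sources used here. F4 was further grown in conditions labelled TX_DOX and TX_HI_FGF. Each of these 9 conditions had 3 libraries. C3.1 cells in TX were also sorted on Cdx2-GFP into 14 populations with labels of 1 to 3 letters, where H stands for high and L for low, with 1 library each. Total counts per library lay between 2213748 and 3641422. The 3 libraries of a condition are technical replicates, so the adjusted p-values, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, measure only technical spread.

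**Figure D1:**
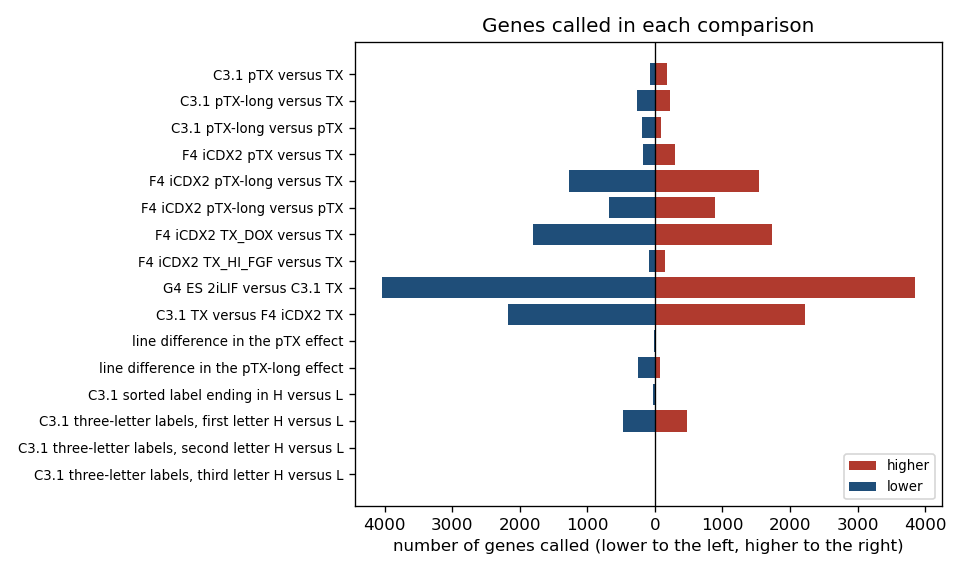
Number of genes called at an adjusted p under 0.05 in each comparison (horizontal axis, genes), with genes higher in the first-named group to the right and genes lower in it to the left of 0. The counts run from 2 for the second letter of the sort labels to 7894 between ES cells and C3.1.

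Most trophoblast genes tested were lower, and most naive pluripotency genes higher, in ES cells than in C3.1 cells in TX. Eomes, a T-box factor of trophoblast stem cells, was lower in ES cells (log2 fold change -6.14 ± 0.13 SE, adjusted p = 1.7e-26, n = 3 and 3), and so was Krt18, a trophectoderm keratin (-7.08 ± 0.17, adjusted p = 1.03e-24). Elf5, which marks the trophoblast stem cell state, was counted 1110-fold lower in ES cells (95% interval 199 to 43900), and Hand1, a giant cell regulator, 635-fold lower (175 to 5250). Among pluripotency genes Tdgf1 was at least 923-fold, Dppa3 at least 194-fold and Prdm14 at least 77.9-fold higher in ES cells, while Fgf4 was 408-fold higher (139 to 1980). Esrrb and Sox2, which both cell types use, were higher in ES cells by 0.75 ± 0.12 (adjusted p = 3.37e-06) and 0.67 ± 0.10 (adjusted p = 1.14e-06) on the log2 scale. Tfap2c was lower at -1.10 ± 0.13 (adjusted p = 1.16e-08), and Gata3 at -2.69 ± 0.17 (adjusted p = 5.1e-15). Krt8, whose count is uncertain because 26.9% of its sequence is shared with other genes, stood at -4.79 ± 0.44 (adjusted p = 4.83e-11), and Ascl2 at -0.03 ± 0.33 was not called. The pluripotency factor gene Pou5f1 had 4, 9 and 4 counts in the ES libraries and 0 in C3.1 in TX, did not pass the filter on low counts and was not tested. The cause of these low counts is open.

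The naming rule, which orders genes by fitted values, took as higher in ES cells Stmn2 (chromosome 3, 8509527 to 8561604, GRCm38; at least 3300-fold), Tdh (threonine dehydrogenase of mouse ES cells, at least 2280-fold), Calcoco2 (at least 1170-fold), Ifitm1 (at least 868-fold) and Trh (at least 554-fold), with Tdgf1 among them. As lower it took Il5ra (at least 255-fold lower), Tmem114 (252), Cd44 (237), Cx3cl1 (230), Gdf6 (201) and Bmp1 (193). Each of these folds is a lower bound, and they give no order among themselves or against Elf5 and Hand1. Of the 14 naive pluripotency genes tested, 11 were higher and 2 lower in ES cells, over all genes as well as adjusted over the list alone (camera adjusted p = 5.01e-14). The trophoblast stem cell list had 3 of 15 higher and 11 lower (the same counts adjusted over the list alone, adjusted p = 1.21e-08). For the trophectoderm list 3 of 20 were higher and 15 lower (the same counts adjusted over the list alone, adjusted p = 2.78e-07). The ectoplacental cone list had 0 of 10 higher and 6 lower, with equal counts adjusted over the list alone (adjusted p = 0.00076). Among 15 cholesterol synthesis genes 14 were lower and 0 higher, also adjusted over the list alone (adjusted p = 4.96e-07), for example Mvd (-2.73 ± 0.15, adjusted p = 3.26e-16) and Sc5d (-2.55 ± 0.11, adjusted p = 1.87e-18). Primitive endoderm genes went both ways, with 2 of 11 higher and 8 lower, also adjusted over the list alone (adjusted p = 0.0021). The lipid carrier Apoe was higher by 5.37 ± 0.18 (adjusted p = 1.93e-21) and the basement membrane collagen Col4a2 was lower at -5.94 ± 0.17 (adjusted p = 3.52e-23). FGF and ERK targets were lower in 12 of 14 and higher in 1 (13 and 1 adjusted over the list alone, adjusted p = 5.29e-06), and adjusted p = 0.0585 with an estimated correlation. Spry4, a feedback inhibitor of this pathway, stood at -5.91 ± 0.30 (adjusted p = 3.43e-17). The lists of WNT targets (5 of 8 higher, 2 lower), BMP targets (2 of 6 higher, 3 lower) and cAMP targets (1 of 8 higher, 4 lower), with the same counts adjusted over the list alone, did not pass (adjusted p = 0.0734, 0.451 and 0.612). In all, 7894 of 11768 genes were called, 3851 higher and 4043 lower in ES cells, and 1981 and 2523 of them differed at least 2-fold.

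C3.1 and F4 cells differed widely in the same medium. The imprinted growth regulator RNA H19 (chromosome 7, 142575530 to 142578146) was lower in C3.1 at a log2 fold change of -10.68 ± 0.22 (adjusted p = 1.14e-25), as was the imprinted gene Dlk1 at -5.36 ± 0.26 (adjusted p = 2.53e-16). Vim, the intermediate filament of mesenchymal cells, was counted 598-fold higher in C3.1 (165 to 4940). The Y-linked genes Ddx3y and Eif2s3y were at least 1240-fold and at least 313-fold higher in C3.1, with 0 counts in F4, and the phospholipase gene Pla2g10 was 34.1-fold lower (11.3 to 169). Eomes, Esrrb and Sox2 were higher in C3.1 by 0.89 ± 0.08 (adjusted p = 6.03e-10), 0.92 ± 0.13 (adjusted p = 1.63e-06) and 0.63 ± 0.10 (adjusted p = 1.47e-05). Ascl2, a factor of the ectoplacental cone, was lower at -1.94 ± 0.27 (adjusted p = 8.71e-07), and Hand1 at -1.63 ± 0.19 (adjusted p = 5.39e-08). Elf5 was lower at -0.30 ± 0.10 (adjusted p = 0.023), a call lost without F4 replicate 3 or any C3.1 replicate (adjusted p up to 0.135) and without a filter (adjusted p = 0.0504). Gata3 (0.06 ± 0.14), Tfap2c (-0.20 ± 0.13) and Krt8 (uncertain, -0.11 ± 0.22) were not called.

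Of 14 imprinted genes tested between both lines 1 was higher and 6 lower in C3.1 (4 and 7 adjusted over the list alone, camera adjusted p = 6.42e-09). Glycolysis and hypoxia genes were lower in 11 of 15 and higher in 1 (11 and 2 adjusted over the list alone, adjusted p = 1.92e-08), among them the glucose transporter Slc2a3 (-1.99 ± 0.12, adjusted p = 9.8e-14) and Ldha (-1.42 ± 0.10, adjusted p = 5.11e-13). TGF-beta and activin targets were higher in 6 of 11 (7 adjusted over the list alone, adjusted p = 0.00432), led by Serpine1 at 1.41 ± 0.13 (adjusted p = 4.97e-10). FGF and ERK targets were higher in 9 of 14 and lower in 1 (10 and 1 adjusted over the list alone, adjusted p = 8e-06), and adjusted p = 0.074 with an estimated correlation. Ectoplacental cone genes were lower in 8 of 10 and higher in 2, also adjusted over the list alone (adjusted p = 0.00935), and adjusted p = 0.0677 with an estimated correlation. The mesenchymal list had 5 of 9 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.00935), and adjusted p = 0.0601 with an estimated correlation. In all 4394 genes were called, 2216 higher and 2178 lower in C3.1.

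Cdx2, the gene of a transcription factor that specifies trophectoderm (chromosome 5), was counted at low levels throughout, and the libraries labelled TX_DOX did not hold more of it. F4 cells in TX had 12.02 ± 4.86 CPM (mean ± SD, n = 3), and the libraries labelled TX_DOX 6.395 ± 1.70, a log2 fold change of -0.93 ± 0.35 (adjusted p = 0.0412). The tags DOX and iCDX2 could be read as CDX2 raised by doxycycline, a reading that the sources used here do not state. The mouse Cdx2 counts do not show such a rise and cannot decide whether an added copy was raised. The call ended when 1 of 4 libraries (TX replicates 1 and 3, TX_DOX replicates 2 and 3) was left out, with adjusted p up to 0.231, and under DESeq2 (adjusted p = 0.0933). Mouse Cdx2 is what was counted, and the sources used here do not say whether an added copy would be counted with it. Cdx2 stood at 13.76 ± 1.69 CPM in TX_HI_FGF (log2 fold change against TX 0.18 ± 0.31), 12.4 ± 4.77 in pTX (0.02 ± 0.31) and 17.59 ± 4.23 in pTX-long (0.53 ± 0.30), none of them called. C3.1 cells in TX had 0.89 ± 0.95 CPM, a log2 fold change of -3.79 ± 0.51 against F4 (adjusted p = 4.52e-07), and ES cells 0.4064 ± 0.428. In C3.1 the Cdx2 counts of 0 to 7 per library were too few to show a difference between media or between sorted populations.

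**Figure D2:**
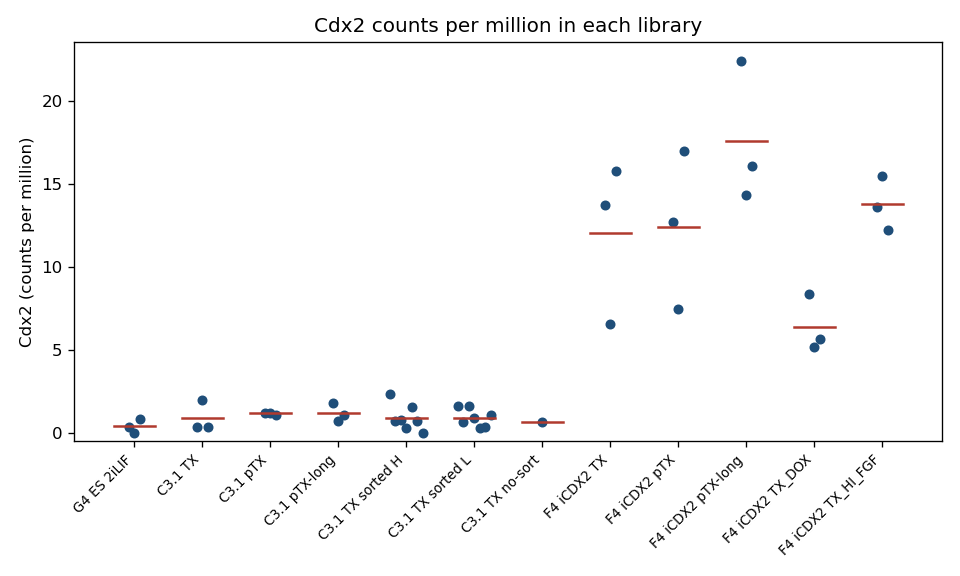
Cdx2 in CPM (vertical axis) for each library (points) of each group (horizontal axis), with group means as red lines. The 3 libraries labelled TX_DOX lie between 5.18 and 8.34, and the 3 F4 libraries in TX between 6.55 and 15.8.

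In pTX, C3.1 cells raised some targets of the cytokine factor STAT3 and of TGF-beta signalling. Socs3, the feedback inhibitor of JAK and STAT signalling (chromosome 11, 117966079 to 117970336), rose by 2.36 ± 0.17 on the log2 scale (adjusted p = 9.38e-11, n = 3 and 3), and Bcl3 by 1.99 ± 0.25 (adjusted p = 8.1e-06). Lefty2, a secreted inhibitor of NODAL and target of it (chromosome 1, 180893108 to 180899107), rose by 2.66 ± 0.39 (adjusted p = 7.52e-05). Wdr72 rose by 2.83 ± 0.38 (adjusted p = 2.19e-05), the protease inhibitor gene Serpinb1a by 2.57 ± 0.22 (adjusted p = 5.07e-09) and Ly6g6e by 2.38 ± 0.33 (adjusted p = 3.77e-05). Of the falling genes that the naming rule took for size, AU015836 kept its call with each library left out (-1.40 ± 0.21, adjusted p = 7.81e-05). The others lost it: Synpo2l (-1.45) and Limch1 (-1.31) without TX replicate 2 or pTX replicate 3 (adjusted p up to 0.0599 and 0.102) and Gadd45b (-1.07) without TX replicate 1 or 2 or pTX replicate 1 (up to 0.117). Bach2 (-1.04) lost it without TX replicate 1 or 2 or pTX replicate 3 (up to 0.0983) and Sept4 (-1.03) without TX replicate 3 (0.0532).

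STAT3 and interleukin-6 family targets rose in 3 of 11 and fell in 1 (3 and 2 adjusted over the list alone, camera adjusted p = 4.51e-06). TGF-beta and activin targets rose in 3 of 11 with 0 falling (4 and 0 adjusted over the list alone, adjusted p = 4.51e-06). Without TX replicate 1 or pTX replicate 1 only 1 of them was called, though the list passed with each library left out (adjusted p up to 7.14e-05). The trophoblast stem cell list had 0 of 15 rising and 1 falling (0 and 3 adjusted over the list alone, adjusted p = 0.0142; up to 0.102 without TX replicate 3 or pTX replicate 2). That gene was Id2, an inhibitor of basic helix-loop-helix factors, at -0.69 ± 0.10 (adjusted p = 0.000126; 2 fell without TX replicate 1, with DESeq2 and in a fit of these groups alone, and 3 without a filter), while Eomes (-0.10 ± 0.08), Elf5 (-0.24 ± 0.10), Esrrb (0.01 ± 0.12) and Sox2 (-0.06 ± 0.10) were not called. Within the trophectoderm list 1 of 20 rose and 2 fell (2 and 3 adjusted over the list alone, adjusted p = 0.015; 0.124 without pTX replicate 2), the latter being Tacstd2 (-1.01 ± 0.17, adjusted p = 0.000514) and the sodium pump gene Atp1b1 (-0.80 ± 0.11, adjusted p = 3.42e-05). Gata3 rose by 0.66 ± 0.14 (adjusted p = 0.00716; up to 0.0627 without TX replicate 2 or pTX replicate 3). Ascl2 fell at -1.39 ± 0.36 (adjusted p = 0.0348), a call lost without TX replicate 2 or 3 or any pTX replicate (adjusted p up to 0.169). Tfap2c (0.19 ± 0.12), Krt8 (uncertain, 0.15 ± 0.21) and Hand1 (0.23 ± 0.19) were not called. Mesenchymal genes rose in 2 of 9 (4 adjusted over the list alone, adjusted p = 2.02e-05), namely Vim (0.79 ± 0.11, adjusted p = 2.77e-05) and Fn1 (0.77 ± 0.15, adjusted p = 0.00232). Primitive endoderm genes rose in 2 of 11 (3 adjusted over the list alone, adjusted p = 2.22e-05), in 0 without TX replicate 3 or pTX replicate 2 and in 1 without pTX replicate 3. Of 4 giant cell genes 1, the prolactin family gene Prl2a1, rose (3 adjusted over the list alone, adjusted p = 0.000163). Wnt3 was the 1 gene to rise among 4 tested of the primitive streak list (2 adjusted over the list alone, adjusted p = 0.0108; 0.0501 without pTX replicate 2), by 3.18 ± 0.56 (adjusted p = 0.000589). Cholesterol synthesis genes rose in 1 of 15 (1 adjusted over the list alone, adjusted p = 0.00249), and in 0 without TX replicate 3. No p53 target was called, yet the list lay lower (0 of 12 rising, 0 falling, 0 and 2 adjusted over the list alone, adjusted p = 0.000163). In all 245 genes were called, 173 up and 72 down, 60 of them by at least 2-fold. Leaving out TX replicate 1, 2 or 3 or pTX replicate 3 left 145, 136, 136 and 136, and testing without a filter on low counts gave 396.

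In C3.1 cells in pTX-long Socs3 was higher than in TX (1.93 ± 0.18, adjusted p = 1.89e-08). Fibronectin, Fn1 (chromosome 1, 71585473 to 71653280), rose by 2.04 ± 0.14 (adjusted p = 6.9e-11), and the homeobox genes Hoxc9 and Irx1 by 2.01 ± 0.20 (adjusted p = 1.13e-07) and 1.82 ± 0.25 (adjusted p = 5.71e-05). Lefty2 rose by 1.89 ± 0.42 (adjusted p = 0.00763; 0.055 without TX replicate 1). AU015836 fell at -2.30 ± 0.24 (adjusted p = 1.81e-07), Tacstd2 at -1.48 ± 0.19 (adjusted p = 9.77e-06), the ascorbate transporter gene Slc23a1 at -1.52 ± 0.30 (adjusted p = 0.00268) and Parp9 at -1.48 ± 0.22 (adjusted p = 7.51e-05). The small nucleolar RNA Snord89 stood at -3.0 ± 0.61 (adjusted p = 0.00352), and Hnrnpul1 at -1.57 ± 0.36 (adjusted p = 0.00892; 0.0893 without pTX-long replicate 1). The largest fold among genes named by the rule, that of Runx1t1 (4.1 ± 0.84, adjusted p = 0.00336), came from pTX-long replicate 2, with 69.6 CPM against 4.84 and 2.11 in replicates 1 and 3, and was not called without it (adjusted p = 0.204).

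Mesenchymal genes rose in 2 of 9 with 0 falling in pTX-long (5 and 0 adjusted over the list alone, adjusted p = 1.23e-08). TGF-beta targets rose in 3 of 11 (3 adjusted over the list alone, adjusted p = 0.00254; 1 without TX replicate 1), and Serpine1 by 0.88 ± 0.12 (adjusted p = 3.53e-05). STAT3 targets rose in 3 of 11 and fell in 1 (4 and 2 adjusted over the list alone, adjusted p = 0.0088; 0.0589 without pTX-long replicate 2), and adjusted p = 0.0545 with an estimated correlation. Naive pluripotency genes fell in 4 of 14 (6 adjusted over the list alone, adjusted p = 0.000156), led by the factors Klf2 (-1.18 ± 0.12, adjusted p = 1.81e-07) and Tfcp2l1 (-0.85 ± 0.12, adjusted p = 5.1e-05). Glycolysis and hypoxia genes fell in 5 of 15 (8 adjusted over the list alone, adjusted p = 4.27e-05), among them Bnip3 (-0.99 ± 0.17, adjusted p = 0.000701). Only 2 fell without TX replicate 1 or 2, and 3 without pTX-long replicate 1 or 2. The trophectoderm list had 5 of 20 falling and 1 rising (6 and 1 adjusted over the list alone, adjusted p = 0.00254; 2 falling without pTX-long replicate 3), with Krt19 at -0.79 ± 0.16 (adjusted p = 0.00343). Of 15 trophoblast stem cell genes 2 fell and 0 rose (5 and 2 adjusted over the list alone, adjusted p = 0.0425; up to 0.253 without TX replicate 3 or pTX-long replicate 2 or 3), and adjusted p = 0.0545 with an estimated correlation. The number falling was 5 without a filter and 6 in a fit of these groups alone. The genes called were Id2 (-0.83 ± 0.11, adjusted p = 1.19e-05) and Elf5 (-0.44 ± 0.11, adjusted p = 0.013; up to 0.0944 without TX replicate 1 or pTX-long replicate 1 or 3). Gata3 rose by 0.69 ± 0.14 (adjusted p = 0.00388; 0.0538 without pTX-long replicate 1). Not called were Eomes (-0.09 ± 0.08), Esrrb (0.22 ± 0.12), Sox2 (-0.29 ± 0.10), Tfap2c (0.06 ± 0.13), Krt8 (uncertain, -0.07 ± 0.22) and Hand1 (-0.19 ± 0.20), and Ascl2 fell at -1.80 ± 0.40 (adjusted p = 0.00659). In all 497 genes were called, 226 up and 271 down, and 182, 212, 218 and 242 without TX replicate 1, TX replicate 2, pTX-long replicate 1 and pTX-long replicate 3. Malat1, named after its values were seen, fell at -0.52 ± 0.14 (adjusted p = 0.025), and Rn45s was not called (-0.59 ± 0.23, adjusted p = 0.15).

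Set directly against pTX in C3.1, pTX-long had more Fn1 (1.26 ± 0.13, adjusted p = 7.71e-07) and less of the galectin gene Lgals9 (-1.94 ± 0.25, adjusted p = 2.12e-05) and of Epas1, the hypoxia factor HIF-2-alpha (-1.56 ± 0.17, adjusted p = 1.7e-06). Prdm1 fell at -1.42 ± 0.16 (adjusted p = 1.7e-06) as the called gene of 10 on the ectoplacental cone list (5 adjusted over the list alone, camera adjusted p = 0.000441). On that list 2 fell without pTX replicate 2, with DESeq2 and in a fit of these groups alone, and 3 without a filter. Naive pluripotency genes fell in 2 of 14 (6 falling and 1 rising adjusted over the list alone, adjusted p = 0.000499; 1 falling without pTX-long replicate 3), Tfcp2l1 at -0.96 ± 0.12 (adjusted p = 1.04e-05). YAP and TEAD targets rose in 2 of 12 (4 adjusted over the list alone, adjusted p = 0.000441), and adjusted p = 0.0575 with an estimated correlation. They rose in 0 or 1 with any library left out, in 1 with DESeq2 and in 4 without a filter. Axl (1.26), Six3 (1.03) and Pga5 (-1.72) were called with all libraries. Axl lost the call when any pTX library or pTX-long replicate 1 or 2 was left out (adjusted p up to 0.128). Six3 lost it when pTX replicate 1 or 2 or any pTX-long library was (up to 0.149), and Pga5 when pTX replicate 3 or pTX-long replicate 2 or 3 was (up to 0.139). Eomes (0.01 ± 0.08), Elf5 (-0.21 ± 0.11), Esrrb (0.21 ± 0.12), Sox2 (-0.23 ± 0.10), Gata3 (0.02 ± 0.14), Tfap2c (-0.13 ± 0.12), Krt8 (uncertain, -0.22 ± 0.21), Ascl2 (-0.41 ± 0.46) and Hand1 (-0.43 ± 0.19) were not called. Between these media 283 genes were called, 98 up and 185 down. The count was 174 in a fit of these groups alone, and 179, 151, 139 and 141 without pTX replicate 2 and pTX-long replicates 1, 2 and 3.

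F4 cells in pTX raised TGF-beta and activin targets. Lefty2 rose by 2.89 ± 0.49 (adjusted p = 0.000265), Serpine1, the plasminogen activator inhibitor and a classic TGF-beta target, by 1.6 ± 0.13 (adjusted p = 6.41e-10) and Pmepa1 by 0.77 ± 0.12 (adjusted p = 6.28e-05). Of 11 such targets 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.24e-12), and 3 rose in a fit of these groups alone. Ly6a rose by 2.29 ± 0.17 (adjusted p = 1.85e-10), Serpinb1a by 2.28 ± 0.24 (adjusted p = 1.67e-07) and Tns4 by 1.71 ± 0.18 (adjusted p = 1.76e-07). Wdr72 rose by 1.71 ± 0.25 (adjusted p = 4.15e-05) and Cebpa by 1.78 ± 0.36 (adjusted p = 0.00215; 0.0523 in a fit of these groups alone). The imprinted placental growth inhibitor Phlda2 (chromosome 7, 143501545 to 143503145) fell at -2.27 ± 0.17 (adjusted p = 1.85e-10), Capn6 at -1.72 ± 0.32 (adjusted p = 0.000976), Nr0b1 at -1.64 ± 0.24 (adjusted p = 4.27e-05) and Plac1 at -1.60 ± 0.30 (adjusted p = 0.000976). Rsad2 and Isg15, which interferon induces, fell at -1.67 ± 0.31 (adjusted p = 0.000826) and -1.60 ± 0.29 (adjusted p = 0.000749).

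Ectoplacental cone genes moved in both directions in F4 pTX, with 5 of 10 rising and 3 falling (6 and 3 adjusted over the list alone, adjusted p = 0.357), and 3 rising without TX replicate 3, with DESeq2 or in a fit of these groups alone. Tpbpa rose by 2.20 ± 0.40 (adjusted p = 0.00114), and Ascl2 fell at -1.49 ± 0.25 (adjusted p = 0.000249). The trophectoderm list had 4 of 20 rising and 1 falling (6 and 4 adjusted over the list alone, adjusted p = 0.0272; up to 0.0977 without TX replicate 2 or 3 or pTX replicate 3), and adjusted p = 0.088 with an estimated correlation. Its keratins rose, Krt18 by 0.75 ± 0.09 (adjusted p = 3.03e-06) and Krt8, whose count is uncertain because 26.9% of its sequence is shared, by 1.27 ± 0.19 (adjusted p = 6.28e-05). Eomes rose by 0.38 ± 0.08 (adjusted p = 0.00598), a call lost without TX replicate 1 (adjusted p = 0.07) and in a fit of these groups alone (adjusted p = 0.142). Sox2 was at -0.34 ± 0.10 and not called (adjusted p = 0.0625), nor were Elf5 (-0.06 ± 0.10), Gata3 (0.13 ± 0.14), Esrrb (0.19 ± 0.13), Tfap2c (0.00 ± 0.12) and Hand1 (-0.07 ± 0.18). Primitive endoderm genes rose in 2 of 11 (6 rising and 1 falling adjusted over the list alone, adjusted p = 0.00259), in 1 without TX replicate 1 or in a fit of these groups alone and in 4 with DESeq2. Fn1, higher by 1.56 ± 0.12 (adjusted p = 5.88e-10), was the mesenchymal gene called among 9 (1 adjusted over the list alone, adjusted p = 0.0148), and adjusted p = 0.0705 with an estimated correlation. Imprinted genes fell in 4 of 14 and rose in 1 (5 and 2 adjusted over the list alone, adjusted p = 0.0174; 0.0524 without pTX replicate 3), and adjusted p = 0.0705 with an estimated correlation. Only 2 fell without TX replicate 1 or in a fit of these groups alone. Altogether 473 genes were called, 304 up and 169 down. The pTX libraries of F4 were spread widely, with a mean chi-square per gene of 14.31 and 8.76 for replicate 2 against replicates 1 and 3 and 5.04 between replicates 1 and 3, and 424 genes were called without replicate 2. A fit of these groups alone called 122, and 245 and 284 were called without TX replicates 1 and 3.

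In F4 pTX-long Serpine1 (chromosome 5, 137061504 to 137072272) rose by 3.09 ± 0.13 (adjusted p = 7.17e-17), Irx1 by 3.34 ± 0.36 (adjusted p = 8.29e-08) and the neuropeptide precursor gene Vgf by 3.05 ± 0.25 (adjusted p = 2.27e-10). The vasodilator peptide gene Adm rose by 2.87 ± 0.45 (adjusted p = 1.75e-05), the matrix protease gene Mmp9 by 2.76 ± 0.14 (adjusted p = 1.84e-15) and Ly6a by 2.72 ± 0.17 (adjusted p = 7.12e-13). Capn6 fell at -3.31 ± 0.40 (adjusted p = 3.42e-07), Phlda2 at -2.71 ± 0.17 (adjusted p = 1.01e-12), AU015836 at -2.67 ± 0.18 (adjusted p = 3.21e-12) and Il17re at -2.55 ± 0.42 (adjusted p = 3.39e-05). The interferon-induced genes Rsad2 and Rtp4 fell at -2.82 ± 0.35 (adjusted p = 6.3e-07) and -2.65 ± 0.36 (adjusted p = 2.62e-06). Trophoblast stem cell genes rose in 6 of 15 and fell in 3, also adjusted over the list alone (camera adjusted p = 0.274). Eomes rose by 0.69 ± 0.08 (adjusted p = 2.9e-07), Esrrb by 0.82 ± 0.13 (adjusted p = 2.53e-05) and Ets2 by 1.23 ± 0.13 (adjusted p = 5.33e-08). Nr0b1 fell at -1.51 ± 0.24 (adjusted p = 2.53e-05), Id2 at -1.05 ± 0.10 (adjusted p = 1.31e-08) and Sox2 at -0.31 ± 0.10 (adjusted p = 0.0313; up to 0.166 without TX replicate 2 or 3 or pTX-long replicate 1 or 2). Gata3 rose by 0.63 ± 0.14 (adjusted p = 0.00154), Gata2 fell at -2.15 ± 0.29 (adjusted p = 2.39e-06) and Ascl2 at -2.28 ± 0.28 (adjusted p = 3.65e-07). Krt8, an uncertain count, rose by 1.0 ± 0.20 (adjusted p = 0.000378), while Elf5 (-0.13 ± 0.10), Tfap2c (-0.01 ± 0.12) and Hand1 (-0.46 ± 0.18) were not called. Of genes named after their values were seen, the ribosomal RNA precursor Rn45s took 0.253 to 0.455% of counts in pTX-long against 0.786 to 1.12% in TX (-1.31 ± 0.23, adjusted p = 0.00011), and the nuclear RNA Malat1 0.288 to 0.411% against 0.582 to 0.641% (-0.70 ± 0.14, adjusted p = 0.00029).

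TGF-beta targets rose in 6 of 11 F4 genes tested and fell in 0, also adjusted over the list alone (adjusted p = 1.17e-10). Fn1 rose by 2.63 ± 0.13 (adjusted p = 1.29e-15) in a mesenchymal list with 2 of 9 rising (2 adjusted over the list alone, adjusted p = 0.001; 1 without TX replicate 1 or pTX-long replicate 3). FGF and ERK targets rose in 6 of 14 (7 adjusted over the list alone, adjusted p = 0.000783), and adjusted p = 0.203 with an estimated correlation. Phlda1 (1.73 ± 0.12, adjusted p = 7.09e-12) and Spry2 (0.97 ± 0.19, adjusted p = 0.000256) were among them. STAT3 targets rose in 5 of 11 and fell in 1 (5 and 4 adjusted over the list alone, adjusted p = 0.00965), and adjusted p = 0.0867 with an estimated correlation. Glycolysis and hypoxia genes fell in 8 of 15 and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 6.71e-07), with Slc2a3 at -2.41 ± 0.13 (adjusted p = 8.87e-15) and Pdk1 at -1.19 ± 0.16 (adjusted p = 3.24e-06). Imprinted genes fell in 5 of 14 and rose in 2 (7 and 3 adjusted over the list alone, adjusted p = 0.001; 9 and 3 in a fit of these groups alone), with Dlk1 at -1.64 ± 0.16 (adjusted p = 1.31e-08). Syncytiotrophoblast genes fell in 6 of 9 and rose in 2, also adjusted over the list alone (adjusted p = 0.0426; 0.0698 without TX replicate 1), and adjusted p = 0.203 with an estimated correlation. Stress response genes rose in 6 of 14 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.0351), and adjusted p = 0.193 with an estimated correlation. Without TX replicate 1 only 3 rose and the list did not pass (adjusted p = 0.0612). In all 2817 genes were called, 1539 up and 1278 down, and 252 and 383 of them by at least 2-fold.

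Against pTX, pTX-long in F4 raised FGF and ERK targets and trophoblast stem cell genes. Of 14 FGF and ERK targets 8 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 2.05e-11). Dusp6, a phosphatase that limits ERK, rose by 1.70 ± 0.16 (adjusted p = 2.01e-08) and Spry2 by 1.37 ± 0.19 (adjusted p = 1.13e-05). Of 15 trophoblast stem cell genes 7 rose and 1 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0114). Bmp4 rose by 1.23 ± 0.18 (adjusted p = 3.35e-05), Esrrb by 0.63 ± 0.13 (adjusted p = 0.0013) and Eomes by 0.32 ± 0.08 (adjusted p = 0.00886). Serpinb9b rose by 2.50 ± 0.26 (adjusted p = 1.23e-07), the cystine transporter gene Slc7a11 by 1.85 ± 0.23 (adjusted p = 1.77e-06) and Vgf by 1.76 ± 0.20 (adjusted p = 7.9e-07). AU015836 fell at -1.86 ± 0.19 (adjusted p = 7.22e-08), Mxra7 at -1.65 ± 0.32 (adjusted p = 0.000881) and Aldh3b2, an uncertain count with 24.2% of its sequence shared, at -2.39 ± 0.46 (adjusted p = 0.000803). Glycolysis and hypoxia genes fell in 7 of 15 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 1.97e-08). Gata3 rose by 0.50 ± 0.14 (adjusted p = 0.0176), a call lost without pTX replicate 2 or pTX-long replicate 1 or 2 (adjusted p up to 0.0856) and in a fit of these groups alone (adjusted p = 0.0842). Elf5 (-0.07 ± 0.10), Sox2 (0.03 ± 0.10), Tfap2c (-0.01 ± 0.12), Krt8 (uncertain, -0.28 ± 0.17), Ascl2 (-0.78 ± 0.31), Hand1 (-0.39 ± 0.18) and Cdx2 (0.51 ± 0.29) were not called. Rn45s, named after its values were seen, fell at -1.09 ± 0.23 (adjusted p = 0.002), as did Malat1 at -0.71 ± 0.14 (adjusted p = 0.00078). In this comparison too pTX replicate 2 stood farther from the other pTX libraries (mean chi-square 14.31 and 8.76) than those from each other (5.04), and 1927 genes were called without it. All told 1564 genes were called, 890 up and 674 down, but a fit of these groups alone called 165. It called 5 FGF and ERK targets and 1 trophoblast stem cell gene rising and 4 glycolysis and hypoxia genes falling, with Esrrb at adjusted p = 0.104 and Eomes at 0.156, and 964 were called without pTX-long replicate 1 or 2.

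**Figure D3:**
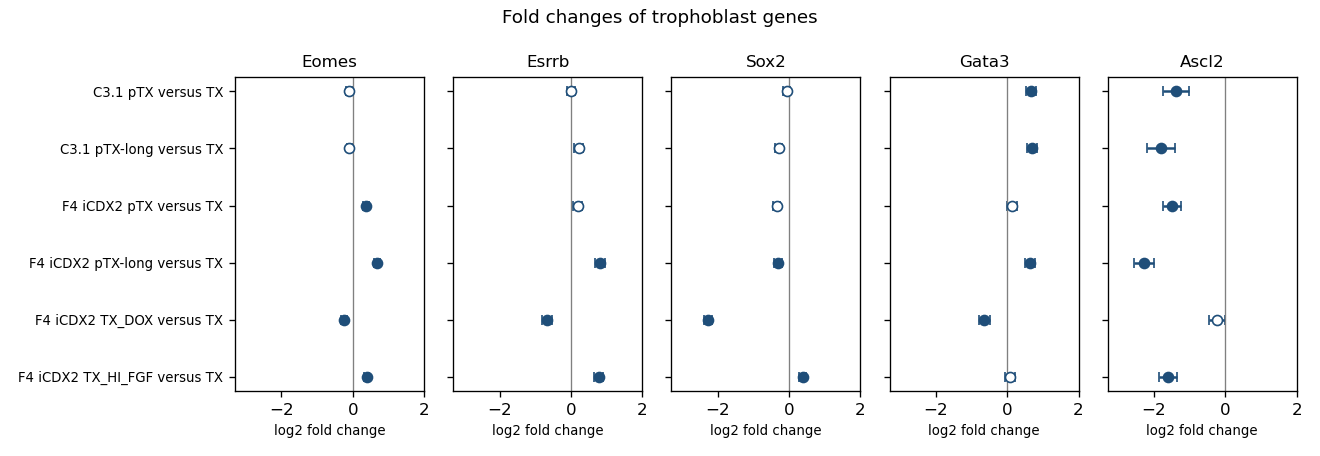
Log2 fold changes (horizontal axes) of 5 trophoblast genes in 6 comparisons (vertical axis), with SE as bars, filled points where the gene was called and open points where it was not. Ascl2 lies between -2.28 and -0.24 in all 6, and Sox2 is lowest, at -2.27, in the libraries labelled TX_DOX.

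The pTX response of both lines shared more calls than independent lists would. C3.1 and F4 share no library, and across 11768 genes, which are not independent replicates, their log2 fold changes for pTX against TX had a Pearson r of 0.206 (Spearman rho 0.262), and 0.393 among 8525 genes with at least 10 CPM. Of the calls, 81 genes were higher in both lines where 4.5 were expected from independent lists, 21 were lower in both against 1 expected, and 1 had opposite signs. For pTX-long against TX the r was 0.36 (rho 0.456), with 159 genes higher in both (29.6 expected), 160 lower in both (29.4 expected) and 12 opposite.

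Tested directly, the pTX effect differed between the lines for 28 genes, 11 more positive and 17 more negative in C3.1. Among the genes named by the rule Phlda2 differed most, by 1.94 ± 0.23 (adjusted p = 3.27e-05), having fallen in F4, and Flt1, a VEGF receptor gene of spongiotrophoblast, by -1.37 ± 0.20 (adjusted p = 0.000436). Gpnmb differed by 1.54 ± 0.28 (adjusted p = 0.00856; 0.112 in a fit of these groups alone) and Ly6a by -1.47 ± 0.23 (adjusted p = 0.000871). Socs3 (1.19 ± 0.24, adjusted p = 0.0213) lost the call without F4 TX replicate 1 or 3, any C3.1 TX library or C3.1 pTX replicate 2 (adjusted p up to 0.117). Tns4 (-1.26 ± 0.26, adjusted p = 0.0224) lost it without F4 TX replicate 2, C3.1 TX replicate 1 or 2 or C3.1 pTX replicate 1 or 2 (up to 0.106). Not called were Eomes (-0.48 ± 0.12, adjusted p = 0.0799), Krt8 (uncertain, -1.12 ± 0.29, adjusted p = 0.104), Elf5 (-0.17 ± 0.15), Esrrb (-0.18 ± 0.18), Sox2 (0.28 ± 0.15), Gata3 (0.53 ± 0.20), Tfap2c (0.19 ± 0.18), Ascl2 (0.11 ± 0.45) and Hand1 (0.31 ± 0.26). In the trophectoderm list 3 of 20 genes were more negative in C3.1 (6 more negative and 1 more positive adjusted over the list alone, camera adjusted p = 2.74e-05; 1 in a fit of these groups alone), Krt18 by -0.91 ± 0.13 (adjusted p = 0.000436). The count was 55 with DESeq2 (21 more positive, 34 more negative), 107 without a filter, where the balance turned to 59 and 48, and 5 in a fit of these groups alone (1 and 4). It was 16, 13 and 17 without F4 TX replicates 1 to 3, 50 without F4 pTX replicate 3, 14 and 16 without C3.1 TX replicates 2 and 3, and 16 and 18 without C3.1 pTX replicates 2 and 3.

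For pTX-long the lines differed in 332 genes, 76 more positive and 256 more negative in C3.1. Capn6 (3.60 ± 0.64, adjusted p = 0.000747), Phlda2 (2.46 ± 0.24, adjusted p = 5.04e-08) and the Kruppel-like factor gene Klf15 (2.29 ± 0.40, adjusted p = 0.000599) were the most positive of those named by the rule. Arhgef6 (-3.42 ± 0.54, adjusted p = 0.00017), Adm (-3.36 ± 0.75, adjusted p = 0.00776; 0.208 without C3.1 TX replicate 1) and Ly6c1 (-2.99 ± 0.61, adjusted p = 0.0029; uncertain, 24.4% shared) were the most negative. Eomes differed by -0.79 ± 0.12 (adjusted p = 8.15e-05), having risen in F4 and not been called in C3.1. Krt8, an uncertain count, differed by -1.07 ± 0.29 (adjusted p = 0.042; up to 0.138 without F4 TX replicate 3, F4 pTX-long replicate 1 or 2, any C3.1 TX library or C3.1 pTX-long replicate 1). Esrrb (-0.60 ± 0.18, adjusted p = 0.0669), Elf5 (-0.31 ± 0.15), Sox2 (0.02 ± 0.15), Gata3 (0.06 ± 0.20), Tfap2c (0.08 ± 0.18), Ascl2 (0.48 ± 0.52) and Hand1 (0.27 ± 0.27) were not called. TGF-beta targets were more negative in C3.1 for 3 of 11 genes (5 adjusted over the list alone, adjusted p = 1.17e-08; 5 without a filter), Serpine1 by -2.22 ± 0.17 (adjusted p = 4.6e-10). FGF and ERK targets were so for 5 of 14 (6 adjusted over the list alone, adjusted p = 2.08e-07; 3 without F4 TX replicate 1, C3.1 TX replicate 1 or C3.1 pTX-long replicate 3), and adjusted p = 0.0711 with an estimated correlation. The count was 194 without F4 TX replicate 1 and 212 without F4 pTX-long replicate 2.

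The libraries labelled TX_DOX differed from F4 in TX in 3537 genes, 1736 higher and 1801 lower (1584 and 1539 with DESeq2). Sox2, a factor that trophoblast stem cells need, was lower at -2.27 ± 0.11 (adjusted p = 8.01e-16), Nr0b1 at -3.24 ± 0.30 (adjusted p = 5.19e-10), Sox21 at -1.62 ± 0.15 (adjusted p = 4.91e-10) and Hand1 at -1.65 ± 0.19 (adjusted p = 5.73e-08). The galectin gene Lgals3 was higher (2.16 ± 0.10, adjusted p = 1.72e-16), as were the tight junction gene Ocln (1.84 ± 0.27, adjusted p = 2.45e-06) and Krt8 (uncertain, 1.99 ± 0.19, adjusted p = 9.25e-10). Ifitm1 was counted 135-fold higher (23.9 to 5380) and the aquaporin gene Aqp9 99.5-fold higher (17.5 to 3970). Tspan1 was higher by 6.19 ± 0.25 (adjusted p = 7.72e-18), Blnk by 5.89 ± 0.20 (adjusted p = 1.37e-19), Csta1 by 5.55 ± 0.43 (adjusted p = 9.33e-12) and Dppa1 by 5.41 ± 0.41 (adjusted p = 5.6e-11). Lower genes taken for size were Arhgef6 (-4.19 ± 0.43, adjusted p = 6.81e-09), the retinol-binding protein gene Rbp1 (-3.69 ± 0.17, adjusted p = 1.71e-16), Dlk1 (-3.69 ± 0.21, adjusted p = 1.5e-14), together with Crispld2 (-3.65 ± 0.28, adjusted p = 1.21e-11), Sox3 (-3.55 ± 0.25, adjusted p = 1.17e-12) and Loxl2, an uncertain count with 45% of its sequence shared (-3.89 ± 0.43, adjusted p = 1.86e-08). Eomes was lower at -0.24 ± 0.08 (adjusted p = 0.0274; up to 0.127 without TX replicate 2 or 3 or TX_DOX replicate 1 or 3, and 0.108 without a filter), Esrrb at -0.66 ± 0.14 (adjusted p = 0.000518), Gata3 at -0.64 ± 0.15 (adjusted p = 0.0011) and Tfap2c at -0.88 ± 0.13 (adjusted p = 2.54e-06). Elf5 (0.22 ± 0.10) and Ascl2 (-0.24 ± 0.23) were not called.

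By list, 9 of 15 trophoblast stem cell genes were lower and 2 higher in the libraries labelled TX_DOX (9 and 4 adjusted over the list alone, camera adjusted p = 0.000237). Trophectoderm and junction genes were higher in 10 of 20 and lower in 3, also adjusted over the list alone (adjusted p = 9.98e-06). YAP and TEAD targets were higher in 7 of 12 (8 adjusted over the list alone, adjusted p = 0.000585), among them Ankrd1 (4.16 ± 0.34, adjusted p = 1.04e-10) and Cyr61 (1.91 ± 0.30, adjusted p = 8.69e-06). Stress response genes were higher in 7 of 14 (8 adjusted over the list alone, adjusted p = 0.000186), with Atf3 at 2.25 ± 0.21 (adjusted p = 4.9e-10) and Ddit3 at 1.63 ± 0.17 (adjusted p = 1.19e-08). Imprinted genes were lower in 8 of 14 and higher in 1 (10 and 1 adjusted over the list alone, adjusted p = 1.64e-06), and the growth factor Igf2 stood at -1.77 ± 0.11 (adjusted p = 1.3e-13). Glycolysis and hypoxia genes were lower in 9 of 15 and higher in 2, also adjusted over the list alone (adjusted p = 0.000237). Giant cell genes were lower in 3 of 4 (4 adjusted over the list alone, adjusted p = 0.00132; 5 lower without a filter). Primitive endoderm genes were lower in 4 of 11 and higher in 2, also adjusted over the list alone (adjusted p = 0.000179). The collagens Col4a1 and Col4a2 stood at -1.64 ± 0.09 (adjusted p = 3.75e-15) and -1.93 ± 0.11 (adjusted p = 5.25e-15), and the factor Gata4 at 1.79 ± 0.32 (adjusted p = 4.28e-05). FGF and ERK targets were higher in 3 of 14 (3 adjusted over the list alone, adjusted p = 0.0118), and adjusted p = 0.295 with an estimated correlation. Without TX replicate 1, 2 were higher and 2 lower.

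In TX_HI_FGF, F4 cells raised feedback targets of FGF and ERK signalling and lowered ectoplacental cone genes. Spry4 and Spry2 rose by 1.38 ± 0.17 (adjusted p = 4.82e-06) and 1.27 ± 0.18 (adjusted p = 9.04e-05), Dusp6 by 1.23 ± 0.15 (adjusted p = 5.03e-06) and Dusp4 by 1.04 ± 0.19 (adjusted p = 0.00159). Of 14 such targets 7 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 4.07e-25), 4 rose without TX replicate 1 and 11 in a fit of these groups alone. Ectoplacental cone genes fell in 5 of 10 with 0 rising (6 and 1 adjusted over the list alone, adjusted p = 4.11e-13), and in 3 without TX replicate 1. Plac1 fell at -2.52 ± 0.33 (adjusted p = 1.75e-05), Ascl2 at -1.61 ± 0.26 (adjusted p = 0.000314) and Phlda2 at -1.34 ± 0.16 (adjusted p = 3.98e-06). Trophoblast stem cell genes rose in 4 of 15 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.000192). Only 2 rose without replicate 1 of TX or TX_HI_FGF, and 8 rose and 3 fell in a fit of these groups alone. Bmp4 rose by 1.21 ± 0.18 (adjusted p = 9.47e-05) and Esrrb by 0.78 ± 0.13 (adjusted p = 0.000637). Eomes rose by 0.39 ± 0.08 (adjusted p = 0.00801; up to 0.135 without TX or TX_HI_FGF replicate 1) and Sox2 by 0.39 ± 0.10 (adjusted p = 0.0393; up to 0.36 with any library but TX replicate 3 left out). Elf5 (-0.06 ± 0.10), Gata3 (0.09 ± 0.14), Tfap2c (-0.24 ± 0.13), Krt8 (uncertain, -0.59 ± 0.23) and Hand1 (0.16 ± 0.18) were not called.

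Other genes that rose in TX_HI_FGF were Acot3 (2.21 ± 0.34, adjusted p = 0.000204), the VEGF receptor gene Kdr (1.71 ± 0.19, adjusted p = 1.23e-06), Sox3 (1.67 ± 0.15, adjusted p = 7.49e-08) and Trim9 (1.27 ± 0.30, adjusted p = 0.0184; up to 0.122 with any library but TX_HI_FGF replicate 2 left out). Rsad2 fell at -1.82 ± 0.32 (adjusted p = 0.000796), Zfp36l3 at -1.47 ± 0.19 (adjusted p = 1.57e-05) and Gata2 at -1.43 ± 0.27 (adjusted p = 0.00205; 0.07 without TX replicate 1). TGF-beta targets lay higher with 0 of 11 called (3 rising adjusted over the list alone, adjusted p = 0.00816; 0.0561 without TX replicate 1), 1 with DESeq2 and 4 in a fit of these groups alone. In all 235 genes were called, 146 up and 89 down. The number was 383 without a filter, 735 in a fit of these groups alone, 71 without TX replicate 1, and 116, 132 and 138 without TX_HI_FGF replicates 1, 2 and 3.

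In C3.1 cells sorted on Cdx2-GFP, few genes differed between labels ending in H and labels ending in L, which were compared in 7 pairs that share all earlier letters. Rhox13, an X-linked homeobox gene (chromosome X, 38120840 to 38129966), was lower in H at a log2 fold change of -2.34 ± 0.24 (adjusted p = 0.000193), with 11.8 ± 7.03 CPM against 62.6 ± 34.1 (SD, n = 7 and 7). The long noncoding RNA Lincenc1 was lower at -1.14 ± 0.16 (adjusted p = 0.00399). Fam111a (-1.18 ± 0.20, adjusted p = 0.0162) and Xlr3c (-1.60 ± 0.32, adjusted p = 0.0444; uncertain, 72.1% shared) lost the call without the pairs HH and HL, HLH and HLL, or LLH and LLL (Fam111a, up to 0.0692) and with any pair but H and L left out (Xlr3c, up to 0.15). Among listed genes Igf2 was higher by 0.35 ± 0.06 (adjusted p = 0.0162; up to 0.0692 without LH and LL, HLH and HLL, or LLH and LLL). Apoe was lower at -0.59 ± 0.12 (adjusted p = 0.0444; up to 0.123 with any pair but H and L left out, and 0.191 with DESeq2). Eomes (0.05 ± 0.07), Elf5 (0.16 ± 0.07), Esrrb (-0.01 ± 0.06), Sox2 (0.12 ± 0.04), Gata3 (-0.02 ± 0.06), Tfap2c (0.03 ± 0.05), Krt8 (uncertain, 0.11 ± 0.10), Ascl2 (-0.29 ± 0.15) and Hand1 (0.09 ± 0.08) were not called. Cdx2 did not pass the filter here or for the letters. In these 7 pairs ectoplacental cone genes lay lower in H with 0 of 9 called (3 lower adjusted over the list alone, camera adjusted p = 0.000216; 1 called lower without H and L or LHH and LHL, and 4 without a filter), and adjusted p = 0.118 with an estimated correlation. In all 37 of 10223 genes were called, 13 higher and 24 lower, and 0 of the higher and 8 of the lower by at least 2-fold, while DESeq2 called 12 higher and 13 lower. Without the pairing the test called 0 genes (617 at an unadjusted p under 0.05) with the number of letters as a term, where Rhox13 stood at adjusted p = 0.0908 and Lincenc1 at 0.282, and 1 with no term. The count was 275 without a filter, 20 in the pairs with 3 letters and 23 in the other pairs. It was 56, 11, 9, 14 and 4 without H and L, HH and HL, LH and LL, HLH and HLL, or LLH and LLL.

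**Figure D4:**
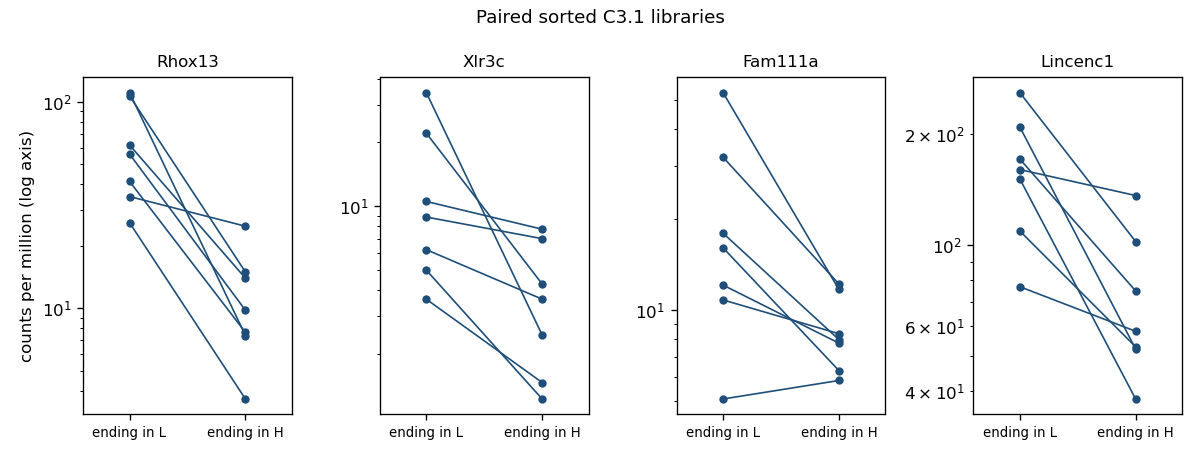
CPM (vertical log axes) of 4 genes in sorted C3.1 libraries whose labels end in L and in H (horizontal axes), with a line joining each of 7 pairs. Rhox13 is lower in H in each pair, and its mean is 11.8 in H against 62.6 in L.

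Labels of 3 letters allowed each position to be tested. The first letter had the most calls, 950 of 9246 genes, 479 higher and 471 lower in H. The 4 libraries with a given first letter share the start of their label and are not shown to be independent populations. Phlda2 was higher by 1.68 ± 0.19 (adjusted p = 0.000554), Plac1 by 1.75 ± 0.30 (adjusted p = 0.00275) and Ascl2 by 0.97 ± 0.20 (adjusted p = 0.00812). Sox2 was lower at -0.40 ± 0.07 (adjusted p = 0.00275), Bmp4 at -0.66 ± 0.12 (adjusted p = 0.00487) and Eomes at -0.47 ± 0.10 (adjusted p = 0.0111; 0.0605 without HHL). Gata3 was higher by 0.48 ± 0.11 (adjusted p = 0.0133; up to 0.0565 without LHL or LLH). Elf5 (-0.23 ± 0.10), Esrrb (-0.17 ± 0.09), Tfap2c (0.12 ± 0.07), Krt8 (uncertain, -0.10 ± 0.16) and Hand1 (0.09 ± 0.11) were not called. The extremes named by the rule were Rpl10l (2.65 ± 0.49, adjusted p = 0.00457), Ifitm3 (1.75 ± 0.22, adjusted p = 0.000858) and Rimklb (2.10 ± 0.49, adjusted p = 0.0138; up to 0.128 without HLH, LHH or LLH, and 0.26 with DESeq2) above. Below were the zinc transporter gene Slc30a3 (-1.91 ± 0.25, adjusted p = 0.000858), Mal (-1.67 ± 0.28, adjusted p = 0.00251) and Prss50 (-1.60 ± 0.14, adjusted p = 6.67e-05). Of 14 trophoblast stem cell genes 5 were lower and 0 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.000201; 3 lower without HHL), and adjusted p = 0.342 with an estimated correlation. Ectoplacental cone genes were higher in 5 of 9 and lower in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.000201), and adjusted p = 0.342 with an estimated correlation. The count was 585 with DESeq2, of which 40.2% were higher in H against 50.4% with edgeR, 1530 without a filter (748 higher, 782 lower), and 444, 502, 442 and 566 without HHL, HLL, LHL and LLH.

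For the second letter 2 genes were called, Rhox13 (-1.53 ± 0.22, adjusted p = 0.021) and Laptm5 (-1.23 ± 0.16, adjusted p = 0.0124). For the third 8 were called, among them Rhox13 (-2.99 ± 0.23, adjusted p = 1.88e-05), Lincenc1 (-1.20 ± 0.18, adjusted p = 0.0199) and the imprinted gene Peg12 (1.02 ± 0.17, adjusted p = 0.0325). With DESeq2 the second letter called 4 and the third 24, and without a filter 82 and 203. Of the genes named in every comparison none was called for either letter, the fold changes running from -0.17 (Krt8, uncertain) to 0.20 (Ascl2) for the second and from -0.36 (Ascl2) to 0.30 (Krt8, uncertain) for the third. The call of Rhox13 for the second letter was lost with DESeq2 (adjusted p = 0.416) and without HHL, HLL, LHL, LLH or LLL (up to 0.378), and that of Laptm5 without HHL or LLL (up to 0.0939). For the third letter Lincenc1 lost its call without LLH or LLL (up to 0.136) and Peg12 with any library but LHH or LHL left out (up to 0.227). The second letter had 0 calls with edgeR (268 at an unadjusted p under 0.05) without HHL, 4 without HLH and 1 without LLL. The third had 17, 5, 3, 17, 72, 4 and 3 without HHH, HHL, HLH, LHH, LHL, LLH and LLL.

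Genes that differed between the sorted populations were then read in the unsorted cultures, which share no library with them. The 24 genes lower in H lay lower in F4 pTX-long than in TX (camera adjusted p = 0.0118; 0.0453 with an estimated correlation and 0.19 with the 100 genes of smallest p). In F4 pTX, C3.1 pTX-long, C3.1 pTX and TX_DOX the same set was not called (adjusted p = 0.0575, 0.0623, 0.774 and 0.226). A set of the 100 genes most clearly higher in H, used because 13 were called, passed in none of the 5 comparisons, the lowest adjusted p being 0.0735 in the libraries labelled TX_DOX.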

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

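The counts over other splits of the libraries were chosen only after the results had been seen. Those splits exchange medium labels within a line, which leaves the response of the other line in place and can itself make a line difference, so they do not bear on chance and only their values are given. The results here stand out because the effect of a medium differed between C3.1 and F4 in an interaction test. Gene by gene, 0 of 28 sets of 7 sorted libraries had an outlying value.

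For pTX the lines differed in 28 genes. The difference, C3.1 minus F4 on the log2 scale, was 1.94 for Phlda2, 1.54 for Gpnmb, 1.19 for Socs3, -1.47 for Ly6a, -1.37 for Flt1 and -1.26 for Tns4. In a fit of these 12 libraries the real labels gave 5 genes, 4 of 30 splits gave as many and the highest of the other splits gave 37.

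For pTX-long 332 genes differed. Capn6 differed by 3.60, Phlda2 by 2.46, Klf15 by 2.29, Arhgef6 by -3.42, Adm by -3.36, Ly6c1 (an uncertain count) by -2.99, Eomes by -0.79 and Krt8 (an uncertain count) by -1.07. In a fit of these 12 libraries the real labels gave 469 genes, 2 of 30 splits gave as many, and the highest of the other splits gave 1903. That split moved 4 libraries of C3.1 and 0 of F4, and so kept the pTX-long response of F4.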

How the results depend on the processing

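Leaving out each library for the letter positions, for the agreement between lines and for gene lists, and the other fits for called members of lists, were chosen only after the results had been seen. No call of a gene named by the rule, gene list test or correlation between the lines turned its direction under any alternative. The signs of other called genes were not compared. The balance of higher and lower calls did turn in some comparisons. Wherever a number moved the cause was not tested. No paired analysis was possible because replicate numbers only name the unsorted libraries, while the sorted ones were paired by label. Leaving an F4 or C3.1 group with fewer libraries keeps a spread pooled over all groups. Total counts of 2213748 to 3641422 per library limit genes with few counts, such as Cdx2 in C3.1.

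With 1 library left out, calls in C3.1 ran from 136 to 184 for pTX against TX (245 with all), from 182 to 489 for pTX-long against TX (497) and from 139 to 194 for pTX-long against pTX (283). In F4 they ran from 245 to 582 for pTX (473), from 1958 to 2732 for pTX-long (2817), from 964 to 1927 for pTX-long against pTX (1564), from 2906 to 2974 for the libraries labelled TX_DOX (3537) and from 71 to 187 for TX_HI_FGF (235). They ran from 7561 to 7669 for ES cells (7894), from 3678 to 3885 between the lines in TX (4394), from 13 to 50 for the line difference in pTX (28) and from 194 to 351 in pTX-long (332). With 1 pair left out the sort gave 4 to 56 (37). The first letter gave 442 to 967 (950), the second 0 to 4 (2; the 0 came from edgeR, with 268 at an unadjusted p under 0.05) and the third 3 to 72 (8). The correlation that measures the agreement of the pTX effect between C3.1 and F4 iCDX2 ran from 0.166 to 0.219 (0.206), and the agreement of the pTX-long effect between C3.1 and F4 iCDX2 from 0.298 to 0.361 (0.36). Among genes with at least 10 CPM they were 0.393 and 0.534.

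Without a filter on low counts there were 396 calls for C3.1 pTX, 383 for TX_HI_FGF, 107 for the line difference in pTX, 275 for the sort and 1530, 82 and 203 for the letters. A fit of only the groups compared gave 174 for C3.1 pTX-long against pTX, 122 for F4 pTX, 165 for F4 pTX-long against pTX, 735 for TX_HI_FGF and 5 for the line difference in pTX. DESeq2 gave 55 for that difference, 585, 4 and 24 for the letters, and 25 for the sort (48% higher in H against 35.1%). The majority of calls turned with DESeq2 for the first letter (235 higher and 350 lower, against 479 and 471), the libraries labelled TX_DOX (1584 and 1539, against 1736 and 1801) and ES cells (3947 and 3927, against 3851 and 4043). It turned with RLE factors for the first letter (471 and 495) and TX_DOX (1788 and 1752), without a filter for the first letter (748 and 782) and the line difference in pTX (59 and 48, against 11 and 17), in a fit of only the groups compared for TX_DOX (2115 and 2051), and in some fits with 1 library left out for TX_DOX, the first letter and the second letter. The sort gave 0 with edgeR without its pairs and with the number of letters as a term (617 at an unadjusted p under 0.05), 1 with no term, 20 in the 4 pairs with 3 letters and 23 in the other 3. The set of genes lower in H had an adjusted p of 0.0458 in C3.1 pTX-long, 0.0309 in F4 pTX and 0.19 in F4 pTX-long when its 100 genes of smallest p were used (0.0623, 0.0575 and 0.0118 with the called genes), and 0.0453 in F4 pTX-long with an estimated correlation.

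Of 344 tests of gene lists 124 passed at the preset correlation, 53 with an estimated one and 158 with fry. Of the 124, 82 passed in every fit with 1 library or pair left out. In 2253 fits of lists with an uneven split of calls, the count on the smaller side stayed in 1953, moved by 1 gene in 263, by 2 in 32 and by up to 5 in the other 5, and the larger side turned in 21. For single named genes, fits with 1 library or pair left out kept the call or its absence in 4893 cases, lost a call in 729 and gained one in 6. DESeq2 did so in 767, 42 and 3, no filter in 823, 15 and 8, and a fit of only the groups compared in 630, 77 and 6. With RLE factors 843 stayed and 3 calls were lost.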

Other observations

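The tests of exchanged labels, of Cdx2 sequence found in other genes and of other splits of the libraries were chosen only after the results they bear on had been seen, as was the size required of the intestinal list.

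Further gene lists separated pTX-long from pTX in F4. Mesenchymal genes rose in 3 of 9 with 0 falling, also adjusted over the list alone (camera adjusted p = 0.0357; up to 0.0871 without pTX replicate 2 or pTX-long replicate 3; adjusted p = 0.102 with an estimated correlation), Fn1 by 1.07 ± 0.11 (adjusted p = 2.75e-07) and the cadherin gene Cdh2 by 1.21 ± 0.34 (adjusted p = 0.0154; up to 0.166 without pTX replicate 1 or pTX-long replicate 3, and 0.133 in a fit of these groups alone). Stress response genes rose in 5 of 14 and fell in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.00548; adjusted p = 0.0598 with an estimated correlation), with the stress factor Atf4 at 0.77 ± 0.14 (adjusted p = 0.000373; 0.0948 in a fit of these groups alone). Imprinted genes fell in 6 of 14 and rose in 1, also adjusted over the list alone (adjusted p = 0.0357; adjusted p = 0.0921 with an estimated correlation), with Peg3 at -0.82 ± 0.19 (adjusted p = 0.00424; 0.0721 in such a fit). A fit of these groups alone called 1 mesenchymal, 0 stress response and 0 imprinted genes, and imprinted genes fell in 3 without replicate 1 of pTX or pTX-long and in 2 without pTX-long replicate 2. In ES cells against C3.1, DNA replication and mitosis genes were higher in 9 of 18 and lower in 1, also adjusted over the list alone (adjusted p = 0.0258; adjusted p = 0.108 with an estimated correlation), with the helicase subunit gene Mcm2 at 1.37 ± 0.09 (adjusted p = 9.34e-14). Stress response genes were lower there in 9 of 14 with 0 higher, also adjusted over the list alone (adjusted p = 0.0281; adjusted p = 0.108 with an estimated correlation), with Trib3 at -3.16 ± 0.21 (adjusted p = 1.77e-14).

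A hypothesis arising from Rsad2 was that interferon-stimulated genes as a group were lower in F4 pTX, pTX-long and TX_HI_FGF than in F4 TX. It was tested on 21 further members of a list of 43, without Rsad2, Isg15, Rtp4 and Parp9. Of these 76.2%, 85.7% and 85.7% lay below 0 in the 3 comparisons (camera adjusted p = 0.0226, 0.00745 and 0.0146 with an estimated correlation), with 3, 7 and 1 of them called lower and 0 higher, as the hypothesis required. The comparisons share the F4 TX libraries, and C3.1 in TX lay below F4 in TX in 20 of the 21 (adjusted p = 0.00745), so a high level in those F4 TX libraries may account for part of it. Without any TX library, F4 pTX-long lay below pTX in 16 of 21 (adjusted p = 0.0146), and C3.1 pTX-long below C3.1 pTX in 19 of 21 (adjusted p = 0.0146), while C3.1 pTX against TX gave adjusted p = 0.663 and the libraries labelled TX_DOX 0.161.

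Cdx2 was not higher in the libraries labelled TX_DOX. An exchange of the TX and TX_DOX labels would leave fewer calls between TX_HI_FGF and the libraries labelled TX_DOX than between TX_HI_FGF and TX, but 3957 were found against 235, which argues against it. Loss of Cdx2 reads to another gene is argued against by the 0% of its 50-base subsequences found in other genes. An added CDX2 copy that the counts do not show may act on intestinal CDX2 target genes, and of the genes tested on an intestinal list 25% were higher, which met the bound of at most 50% that had been set beforehand as evidence against this. That rests on 4 of the 30 list genes in the files (1 called higher, 3 lower). The list was held too small, so this explanation stays open.

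Genes differed by the first letter of the 3-letter labels far more than by the others. A difference in depth is argued against, since 859 genes were called after thinning the 8 libraries to 2550952 counts each, against 950. The populations with 2 letters are other libraries. In them 89.1% of the 950 genes (846) had the same sign between HH, HL and LH, LL. The other splits of these 4 gave 66% and 57.9%, so the difference by first letter was also seen there. These libraries may share starting populations with the 3-letter ones, so that does not show a difference carried by the letter itself. Between the populations H and L the share was 57.1%, near the lowest of those splits, so the difference was not seen between them. Whether the difference among the longer labels reflects Cdx2-GFP at a first sort or separate handling of the descendants of each population was not tested. The order of the letters is not given in the sources used here.

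Genes with near-identical copies had low counts. Across 77 ribosomal protein genes, which are not independent replicates, the share of sequence found in other genes and the mean CPM had a Spearman rho of -0.44, past the bound of -0.4 set beforehand. The 36 genes with at least 20% shared had a median of 44.1 CPM and the other 41 a median of 199. Reads that match several places may therefore have been left out of the deposited counts, and a lower expression of genes with many copies was not tested.

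For the other comparisons the splits were counted in fits of only those libraries. For the sort, 1 of 64 splits, the real one, gave as many as its 37 genes, with 10 the highest of the others. Chance alone is thus unlikely there but not excluded, as the splits were chosen after the result was seen and each label has 1 library. For the first letter 1 of 35 gave as many as 869, with 2 the highest of the others. For the other letters, with edgeR, 0 genes were called, which 35 of 35 splits matched. These fits had no term for the other letters, so the first-letter difference held down calls in other splits. Libraries sharing the start of their label are not exchangeable with others. The splits of letters thus exclude no chance difference between single starting populations. Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real labels and the highest other split gave 216 and 2 for C3.1 pTX, 732 and 0 for pTX-long, 174 and 2 for pTX-long against pTX, 122 and 0 for F4 pTX, 3089 and 0 for pTX-long, 165 and 0 for pTX-long against pTX, 4166 and 0 for the libraries labelled TX_DOX, 735 and 0 for TX_HI_FGF, 7558 and 0 for ES cells and 4826 and 0 between the lines in TX.

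The unsorted C3.1 library that stood in no comparison had 2 counts of Cdx2 (0.642 CPM) and 36.26 CPM of Rhox13, where sorted populations had 11.8 ± 7.03 in H and 62.6 ± 34.1 in L (SD, n = 7 and 7) and C3.1 in TX 24.68. Pou5f1 had 4, 9 and 4 counts in the ES libraries, or 1.46, 4.12 and 1.71 CPM. Of its 50-base subsequences 0.561% occur in other genes, so shared reads are not shown to be the reason, and the cause is open.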
